A study of Macaca fascicularis with 6 samples.

How the data were processed

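Single-cell RNA sequencing of bone marrow mononuclear cells was analysed in 6 cynomolgus macaques (Macaca fascicularis), 3 with a disease like ankylosing spondylitis, called AS here, and 3 healthy controls, called HC. Per the labels, the cells were isolated on Ficoll and captured with the 10x 5' kit, version 2. Each library came from a separate animal: the labels give ages of 10.3, 11.1 and 11.8 years for AS and 12.7, 8.1 and 15.9 years for HC. The animal was the replicate in every test, with n = 3 per group. Group and replicate number were taken from the sample titles. The AS file names carry other numbers than the titles, and the titles were used. Sex, treatment, handling times and sequencing batches were not given in the sources used here.

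The deposited matrices hold counts, per the file headers: whole numbers of UMIs per gene and cell barcode, already filtered to cell barcodes. Per the submitters' processing notes, Cell Ranger 6.1.2 and Seurat 4.0.0 were used. The role of each, the genome build and the annotation release were not given in the sources used here. The files list the same 22323 genes for each library, of which 7186 have an Ensembl ID and no symbol, and 0 of those IDs matched the RefSeq table supplied. They took part in the tests, but no symbol was guessed for them.

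The files held 8439, 7510 and 4934 barcodes for AS_1 to AS_3 and 10507, 4906 and 6215 for HC_1 to HC_3. The total depth was 38527389, 42478770 and 35375215 UMIs in AS and 62313271, 24982760 and 13769652 UMIs in HC. The median per barcode was 3321, 1640 and 5164 UMIs in AS and 3895, 2923.5 and 1093 UMIs in HC. The 10 most abundant genes took 12.1, 24.6 and 11.4% of UMIs in AS and 21.0, 24.0 and 25.6% in HC. Mitochondrially encoded genes took 1.39, 1.59 and 2.45% in AS and 2.11, 1.46 and 1.40% in HC. HC_3 was the shallowest library. AS_2 had the fewest B and NK cells and carried platelet transcripts. HC_3 carried them too: clustered on its own, it had a cluster of 942 cells led by PPBP, SOD2, G0S2 and PF4.

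Barcodes with at least 200 detected genes and at most 10% mitochondrial UMIs were kept. Doublet scores came from Scrublet in scanpy 1.11.5, run on each library. Its automatic call marked between 0 and 2.25% of barcodes per library, so a fixed share with the highest scores was removed instead, 0.8% per 1000 barcodes, which came to between 3.92 and 8.41%. In all, 38108 of 42511 cells were kept: 7721, 6863 and 4573 for AS, and 8949, 4344 and 5658 for HC. Cells were scaled to 10000 counts and logged, and 2000 variable genes were chosen within libraries. Mitochondrial, ribosomal, immunoglobulin and T cell receptor genes were left out of that choice. Of these, 30 principal components and 15 neighbours went into Leiden clustering (igraph 0.11.9) at resolution 1 with seed 0 and without integration across libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

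The 32 clusters were named from 16 marker lists written before the data were examined. The score of a class was the mean z-score of log2(CPM + 10) over its markers, plus 0.5 for each marker of that class alone among the 10 genes with the largest fold in the cluster. A cluster stayed unnamed if no such marker was among the 10, if another class had more there, if fewer than 3 markers were detected at 10 CPM, or if the mean z-score was at most 0.5. These naming rules were adjusted after looking at the clusters. A cluster led by C1QC and C1QA was kept as a class of its own under that name. The 3 clusters left unnamed held 4.49% of AS cells and 0.319% of HC cells on average. Their cells stayed in the denominators of all shares and in the sums over all cells, but formed no class. The 14 classes were compared by their share of kept cells with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. The 5 classes with fewer than 20 cells in any library (NK cells, B precursors, plasmacytoid dendritic cells, megakaryocytes, and stromal or endothelial cells) were not tested for genes.

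UMI counts were summed per library for 9 classes and for all cells. Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM, and tested with the quasi-likelihood fit of edgeR 4.0.16 in R 4.3.3 with robust dispersion. The Benjamini-Hochberg method was applied over the genes of each class at 0.05. Gene lists, 28 in all and written before the data were examined, were tested where at least 5 members were measured. The test was camera of limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a class. A preset correlation takes genes of a list as nearly independent, so p values with an estimated correlation were computed as well, and fry was run beside it. For these lists in the classes and all cells, the lowest adjusted p was 0.0545 with an estimated correlation and 0.0541 by fry. The p of the members was also adjusted over the list alone. The marker lists served to look for other cell types within each class, and their lowest adjusted p by fry was 0.052. In single clusters the lowest adjusted p of the immediate early list with an estimated correlation was 0.0535.

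The genes named in the report were set by a rule fixed before the data were examined. Genes with an adjusted p under 0.05 whose 3 AS values all lay above or all below the 3 HC values were named, up to 10 in each direction with a mean of at least 10 CPM. Of genes without any grouping, 10% would separate in this way by chance. Where fewer than 5 passed, the 5 with the smallest p in each direction qualified as not passing, and of each called list up to 4 members qualified. The text gives a part of these, and 1 gene is withheld and not reported. The genes TNF, IL1B, IL6, IL17A, IL23A, IL23R, ERAP1, ERAP2, TNFRSF1A, S100A8, S100A9 and CXCL8 were named in the class with their highest mean whether called or not. Immunoglobulin and T cell receptor variable segments were not named.

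The edgeR step was tested on simulated counts with the means, dispersions and depths of 4 sums, in which 200 genes were changed. In monocytes it recovered 26.15% of genes changed by 2-fold, 82.09% by 4-fold and 88.89% by 8-fold, with 16 false calls. In CD4 T cells it recovered 20, 87.5 and 100% with 7 false calls, in plasma cells 13.33, 85 and 98.36% with 12, and in all cells summed 3.077, 47.76 and 84.62% with 7. Changes of 2-fold were therefore mostly out of reach.

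Alternatives planned before the data were examined were DESeq2 1.42.0 without the count filter, its size factors in edgeR, no count filter, age as a covariate, the replicate number as a block, each library left out in turn, no doublet removal and a stricter cell filter of 500 genes and 5% mitochondrial UMIs. Further ones were Leiden resolution 2, each library clustered on its own, and shares without erythroid cells and neutrophils. Added afterwards were AS_2 and HC_3 left out together, neutrophils joined, the unnamed T-like cluster counted as CD8 T cells, and single clusters tested alone. Intervals of shares are exact 95% binomial intervals, and the limit at a count of 0 is 3 cells of the total. Both cover counting error only. T cell receptor and immunoglobulin sequences were not analysed here.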

Results

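Bone marrow mononuclear cells of 3 cynomolgus macaques with an ankylosing spondylitis-like disease (AS) were compared with those of 3 healthy controls (HC). The libraries are called AS_1 to AS_3 and HC_1 to HC_3 after the replicate numbers of the labels. Gene values are UMI counts summed per animal and cell class and scaled to the library size (CPM), given as mean ± SD with n = 3 animals per group. Fold changes are on the log2 scale, AS over HC. A list is a set of genes written down before the data were examined, and its test was camera of limma with a preset correlation of 0.01. No list passed at 0.05 in any class once the correlation was estimated from the data, and that adjusted p stands beside each list call below. Marker lists of cell types were tested with the preset correlation too. None of them passed by fry, and that adjusted p stands beside theirs. Members that passed over the list alone are counted where there were any, and members that passed over all genes were only those named as called.

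Neutrophils made up the largest part of the kept cells. Shares are of these Ficoll-isolated cells and not of whole marrow. Neutrophil precursors, which carried MPO, AZU1 and LTF transcripts, held 19.1 ± 4.01% of AS cells and 34.5 ± 13.2% of HC cells. Mature neutrophils held 27.9 ± 18.2% and 23.2 ± 11.8%, and erythroid cells 7.44 ± 6.46% and 15.3 ± 11.4%. CD4 T cells held 9.13 ± 5.19% and 7.94 ± 5.93%, CD8 T cells 5.72 ± 5.08% and 2.82 ± 1.51%, and B cells 5.80 ± 5.35% and 4.17 ± 4.01%. Monocytes held 11.5 ± 11.3% of AS cells and 5.72 ± 1.05% of HC cells, with 24.6% in AS_3. NK cells held 3.30 ± 3.75% and 1.31 ± 0.882%, and plasma cells 1.38 ± 1.30% and 1.52 ± 0.700%. A cluster led by C1QC, C1QA, CD5L, HMOX1, TIMD4 and VSIG4, genes known from tissue macrophages, held 2.20 ± 2.55% and 1.41 ± 0.844%. Plasmacytoid dendritic cells held 0.215 ± 0.141% of AS cells and 0.420 ± 0.0808% of HC cells, B precursors 0.287 ± 0.25% and 0.882 ± 1.05%, megakaryocytes 1.39 ± 2.10% and 0.398 ± 0.283%, and stromal or endothelial cells 0.142 ± 0.136% and 0.137 ± 0.201%. No class passed a test of its share, which says nothing about stability at this number of animals. The lowest p of a two-sided exact permutation test was 0.2, for plasmacytoid dendritic cells, and the second lowest was 0.3, for neutrophil precursors. The smallest p that 3 against 3 allows is 0.1, and plasmacytoid dendritic cells and B precursors reached it, lower in AS, when erythroid cells and neutrophils were left out of the denominator. That denominator kept the unnamed cells, 983 of them in AS_1, which lowered the shares of that library. The test was not run without them. Single libraries carried much of some differences in share: AS minus HC went from -7.843 to -1.498 percentage points for erythroid cells without HC_1, from 2.899 to 0.06617 for CD8 T cells without AS_1, and from -15.41 to -9.112 for neutrophil precursors without HC_3. The lowest adjusted p over the classes was 0.8615, and edgeR on cell numbers per class gave a lowest adjusted p of 0.674, with neutrophil precursors at a log2 change of -0.86 (SE 0.954).

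**Figure D1:**
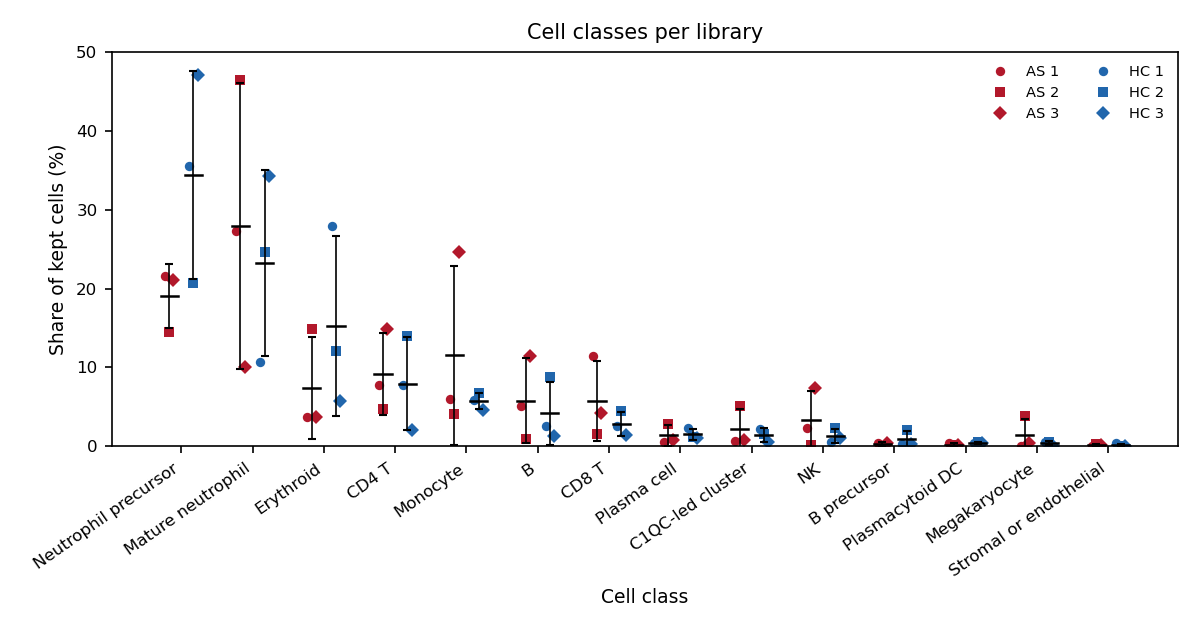
Share of kept cells (%) in each of 14 cell classes. Circles, squares and diamonds are the libraries with replicate numbers 1, 2 and 3, red for AS and blue for HC, and black bars are the mean and SD of 3 animals, with SD bars ending at 0 where they would pass below it. AS and HC libraries overlap in each class, and neutrophil precursors averaged 19.1% in AS and 34.5% in HC.

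TNF, the cytokine that is the target of first-line biological drugs in spondyloarthritis, fell in AS mature neutrophils. It stood at 9.28 ± 4.22 CPM in AS and 242.5 ± 104 CPM in HC, a log2 change of -4.81 (SE 0.467, edgeR adjusted p = 0.03), and each AS library lay below each HC library. CXCL8, the main neutrophil-attracting chemokine, averaged 842 ± 430 CPM in AS and 5893 ± 1870 CPM in HC (adjusted p = 0.0946). EGR1, a transcription factor made within minutes of a stimulus, averaged 15.0 ± 9.83 and 617 ± 348 CPM, and BTG2, an antiproliferative early gene, 326 ± 124 and 2100.0 ± 169 CPM, both with an adjusted p of 0.0614. NFKBIZ, which steers NF-kB to secondary targets, averaged 148 ± 9.33 and 820.4 ± 310 CPM, and the chemokine receptor CCR1 2.38 ± 1.03 and 25.9 ± 2.95 CPM (adjusted p = 0.0614 for both). On the other side, GADD45A, a growth arrest gene, averaged 199.9 ± 26.5 CPM in AS and 53.8 ± 4.83 CPM in HC (adjusted p = 0.0614), and the calcium-binding S100P 1410.0 ± 684 and 322 ± 5.71 CPM (adjusted p = 0.134). The alarmin S100A9 averaged 35400.0 ± 16000.0 and 17130.0 ± 3630 CPM (adjusted p = 0.6). TNF was the only gene of 6251 that edgeR called. At unadjusted p under 0.05 stood 513 genes, and DESeq2 called 74, of which 23 were higher and 51 lower in AS. Without AS_1, AS_2, AS_3 or HC_2 edgeR called 0 genes, without HC_1 it called 2 (DNAJC3 and TNF), and without HC_3 it called 3, TNF among them. The TNF call was also lost with age as a covariate, with the replicate number as a block and with each library clustered on its own. In the last setting the class lacked 942 cells of HC_3 that were named megakaryocytes, led by PPBP, SOD2, G0S2 and PF4. It also lacked 761 cells of AS_1 and 213 of HC_1 that scored best as mature neutrophils but stayed unnamed.

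Immediate early genes, which mark recent stimulation, were lower in AS mature neutrophils as a list. The median log2 change of its 20 measured members was -2.40, only 1 member lay above 0, and 15 members passed over the list alone (camera adjusted p = 3.46e-28, and 0.0974 with an estimated correlation). The TNF and NF-kB response list had a median of -2.07 over 20 members, with 14 lower over the list alone and 1 over all genes (adjusted p = 3.37e-26, and 0.0974 with an estimated correlation). Of 5 chemokines and receptors all were below 0, CXCL1 at 12.9 ± 9.13 and 98.0 ± 65.0 CPM and CCL2 at 3.45 ± 4.76 and 57.5 ± 51.7 CPM among them, with 4 lower over the list alone (adjusted p = 1.31e-13, and 0.0545 with an estimated correlation). The unfolded protein response list was lower with a median of -0.52 and 2 lower over the list alone, led by DNAJC3 and the chaperone HSPA5, which averaged 73.0 ± 17.7 and 202 ± 34.9 CPM (adjusted p = 0.00101, and 0.0974 with an estimated correlation). Ribosomal protein genes were higher with a median of 0.45 in 21 of 21 members (adjusted p = 9.64e-06, and 0.419 with an estimated correlation). These 5 calls held without any 1 library. Granule protein genes were higher with a median of 1.36, PGLYRP1 at 6116 ± 2400.0 and 2390.0 ± 604 CPM (adjusted p = 0.00111, and 0.419 with an estimated correlation), but not without AS_2 (0.229). Nuclear oxidative phosphorylation genes had a median of 0.37 (adjusted p = 0.00595, and 0.477 with an estimated correlation), lost without AS_2 (0.173) and HC_1 (0.053). Mitochondrially encoded genes had a median of 0.46 with the same 2 adjusted p values, lost without AS_2 (0.274) and HC_2 (0.15). Within this class the neutrophil precursor markers were also higher in AS (adjusted p = 1.28e-04) and erythroid markers lower (0.00505), with 0.2601 by fry for both. The clusters joined in the class differed between libraries: 3164 of 3190 cells of the largest came from AS_2, and 1 of the HC-rich clusters was itself led by G0S2, CXCL8 and NFKBIA. That overlaps the genes tested here, so the change could not be separated from the mix of clusters.

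**Figure D2:**
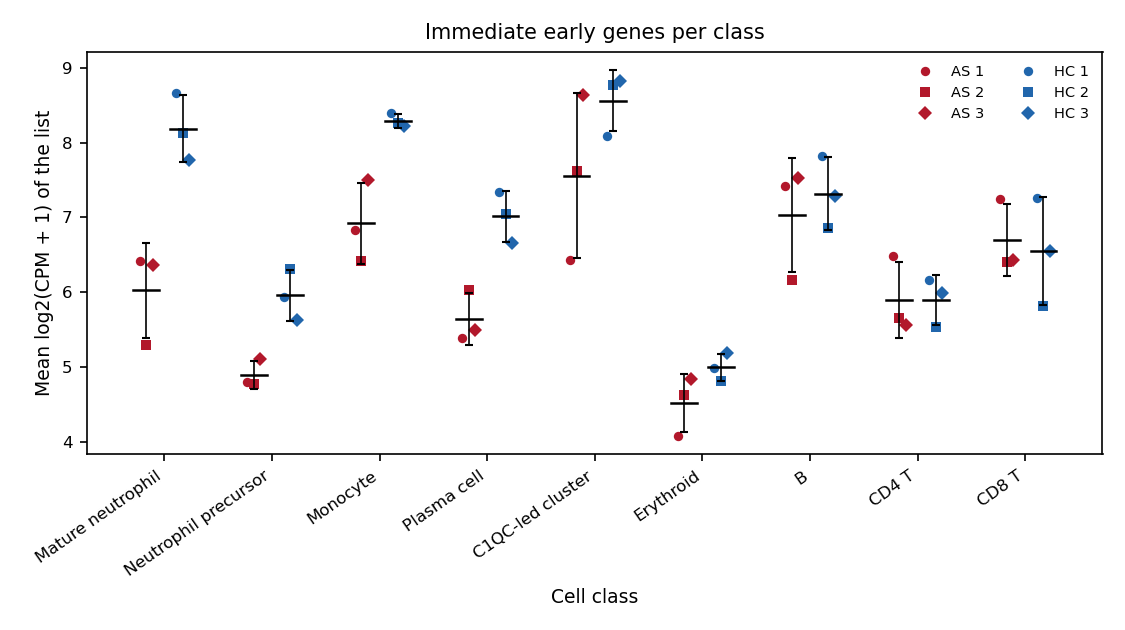
Mean log2(CPM + 1) of the immediate early genes in 9 cell classes. Circles, squares and diamonds are the libraries with replicate numbers 1, 2 and 3, red for AS and blue for HC, with the mean and SD of 3 animals in black. In mature neutrophils the AS libraries lie at 6.42, 5.29 and 6.36 and the HC libraries at 8.66, 8.14 and 7.77, whereas CD4 T and CD8 T cells overlap.

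NR4A1, a nuclear receptor switched on at once by stimulation, fell in AS monocytes. It stood at 11.3 ± 0.822 CPM in AS and 147 ± 55.0 CPM in HC, a log2 change of -3.69 (SE 0.306, edgeR adjusted p = 0.0149), lower in 3 of 3 AS libraries than in any HC library. KLF4, a transcription factor of monocyte differentiation, averaged 161 ± 6.17 and 576 ± 148 CPM, and MYB, a progenitor transcription factor, 2.64 ± 0.136 and 16.4 ± 4.77 CPM (adjusted p = 0.073 for both). The inflammasome sensor NLRP3 averaged 82.3 ± 14.3 and 217 ± 43.4 CPM (adjusted p = 0.112). The cytokines TNF, at 45.5 ± 45.8 and 550.5 ± 244 CPM, IL1B, at 126 ± 115 and 891 ± 560.0 CPM, and IL6, at 2.61 ± 2.54 and 17.5 ± 19.4 CPM, had adjusted p values of 0.285, 0.357 and 0.417. CCR2, the receptor that lets monocytes leave the marrow, averaged 139 ± 13.6 CPM in AS and 52.8 ± 8.03 CPM in HC (adjusted p = 0.073), and the lipid receptor S1PR1 19.4 ± 2.48 and 2.41 ± 1.26 CPM (adjusted p = 0.073). GAS6, a ligand for phagocytic receptors, averaged 30.3 ± 9.62 and 2.01 ± 1.91 CPM (adjusted p = 0.0945). NR4A1 was the only gene of 9504 that edgeR called. A total of 1060 genes had an unadjusted p under 0.05, and DESeq2 called 155, 89 higher and 66 lower. Without AS_3 edgeR called 74 genes, 46 higher and 28 lower, with EGR1 and DUSP2 among the first. Without HC_1 it called 1, NR4A1, and without AS_1, AS_2, HC_2 or HC_3 it called 0. The NR4A1 call was also lost with age as a covariate, with the replicate number as a block, without doublet removal, under the stricter cell filter, with each library clustered on its own, and without AS_2 and HC_3 together.

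Immediate early genes were lower in AS monocytes as well, with a median of -1.25 over 23 members, 15 lower over the list alone and 1 over all genes (adjusted p = 3.87e-23, and 0.228 with an estimated correlation). The TNF and NF-kB response had a median of -0.94, with CD83, a maturation marker, at 42.4 ± 20.4 and 223 ± 45.3 CPM. Of its members 5 were lower and 1 was higher over the list alone, the mitochondrial SOD2 at 1647 ± 402 and 534 ± 148 CPM (adjusted p = 1.77e-11, and 0.324 with an estimated correlation). Cell cycle genes were lower with a median of -0.91 and 6 passing over the list alone, MCM3, part of the replicative helicase, at 10.5 ± 2.10 and 28.4 ± 7.47 CPM (adjusted p = 1.64e-13, and 0.423 with an estimated correlation). MHC class II genes were higher with a median of 0.60 in 12 of 12 members and 1 passing over the list alone, HLA-DRA at 3085 ± 754 and 1709 ± 465 CPM (adjusted p = 1.26e-04, and 0.550 with an estimated correlation). Complement genes had a median of 0.79, with 1 higher over the list alone, the decay factor CD55 at 79.2 ± 9.33 and 37.2 ± 5.54 CPM (adjusted p = 4.08e-04, and 0.228 with an estimated correlation). These 5 calls held without any 1 library. Glucocorticoid response genes had a median of 0.43 with 3 higher over the list alone. Of these, the scavenger receptor CD163 averaged 570.1 ± 191 and 229 ± 15.1 CPM, and FKBP5, a co-chaperone of the glucocorticoid receptor, 126 ± 37.4 and 46.9 ± 16.2 CPM (list adjusted p = 0.0257, and 0.560 with an estimated correlation). That call was lost without AS_1 (0.0958), AS_3 (0.213), HC_2 (0.131) or HC_3 (0.0597). The type I interferon list had a median of 0.43 (adjusted p = 0.00274, and 0.603 with an estimated correlation), lost without AS_2 (0.395), HC_2 (0.0514) or HC_3 (0.187). MHC class I genes had a median of 0.52 (adjusted p = 0.00173, and 0.603 with an estimated correlation), lost without AS_2 (0.184). Granule protein genes had a median of -0.99 (adjusted p = 0.0200, and 0.603 with an estimated correlation), lost without AS_3 (0.245), HC_1 (0.259) or HC_3 (0.0502). Ribosomal protein genes had a median of -0.26 (adjusted p = 0.0257, and 0.603 with an estimated correlation), lost without AS_2 (0.509) or HC_2 (0.0971). Neutrophil precursor markers were lower in AS monocytes (adjusted p = 0.0104, and 0.535 by fry). The HC monocytes came mainly from a cluster led by IL1B, KLF4, TNF and NR4A1, which overlaps the genes tested. AS monocytes lay in other clusters: 1051 of 1124 cells of AS_3 and 315 of 460 of AS_1 in 1 led by CPVL, CD163 and NRG1, and 268 of 279 of AS_2 in 1 led by CDKN1C, CXCL10 and MS4A7. Most AS monocytes thus lay in other clusters than most HC monocytes, and those of AS_2 in another than those of AS_1 and AS_3. The libraries were clustered without integration, and whether these clusters are subtypes was not tested. None of the changes in monocytes was separated from that mix of clusters.

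**Figure D3:**
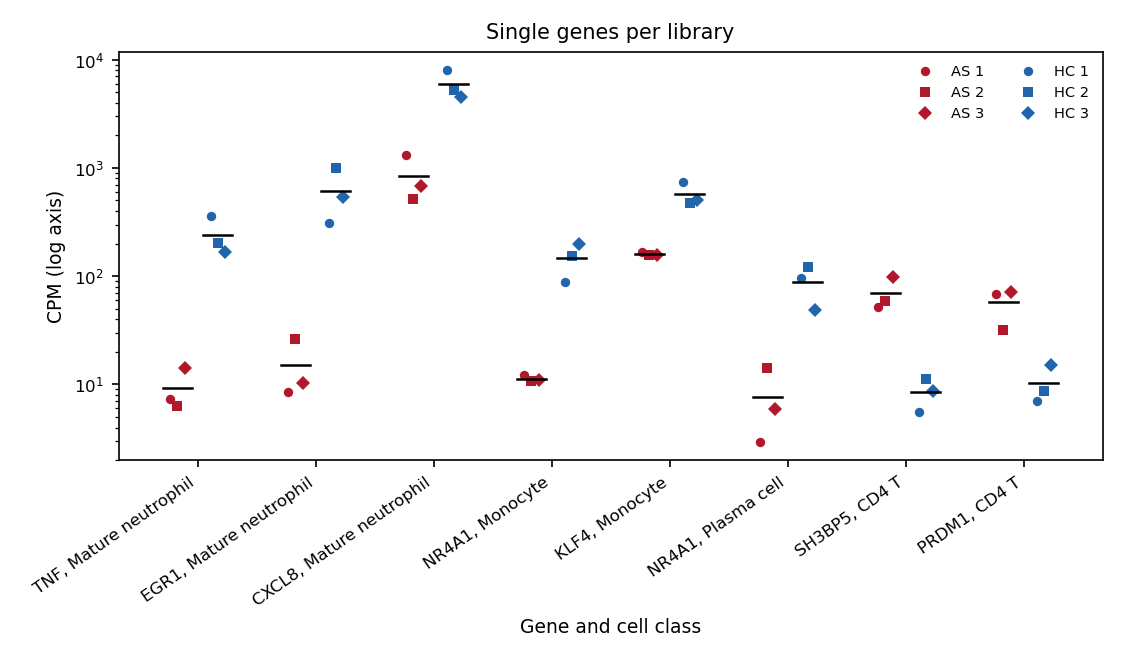
CPM of single genes per library on a log axis. Circles, squares and diamonds are the libraries with replicate numbers 1, 2 and 3, red for AS and blue for HC, and black bars are the means of 3 animals. TNF averaged 9.28 CPM in AS and 242.5 CPM in HC mature neutrophils, and SH3BP5 69.5 and 8.50 CPM in CD4 T cells.

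Neutrophil precursors had lower immediate early genes in AS too. EGR1 averaged 11.5 ± 6.41 CPM in AS and 95.2 ± 36.6 CPM in HC, BTG2 85.6 ± 27.4 and 289 ± 23.6 CPM, NR4A1 0.681 ± 0.253 and 5.97 ± 2.13 CPM, and TNF 4.28 ± 1.63 and 22.9 ± 8.23 CPM, each with an adjusted p of 0.395. CD3D and CD3E, which encode parts of the T cell receptor complex, averaged 31.0 ± 6.67 and 5.69 ± 3.46 CPM, and 28.3 ± 3.72 and 4.52 ± 3.36 CPM (adjusted p = 0.395 for both). The alarmin S100A8, the most abundant of the genes named here, averaged 133200.0 ± 88200.0 and 152700.0 ± 51900.0 CPM (adjusted p = 0.975). Of 9345 genes edgeR called 0, with all 6 libraries and without any 1 of them. At unadjusted p under 0.05 stood 459 genes, and DESeq2 called 56. With the replicate number as a block, 919 genes had an unadjusted p under 0.05 and edgeR called 3: EGR1, PLAAT4 and GAS6, the last 2 named after their values were seen. The immediate early list had a median of -1.03, 21 of 22 members below 0 and 10 lower over the list alone (adjusted p = 3.59e-23, and 0.188 with an estimated correlation). The TNF and NF-kB response had a median of -0.76 with 5 lower over the list alone (adjusted p = 5.16e-09, and 0.206 with an estimated correlation). Cytotoxicity genes were higher with a median of 1.21 and 1 passing over the list alone, GZMK at 12.8 ± 4.09 and 1.34 ± 1.27 CPM (adjusted p = 1.89e-08, and 0.393 with an estimated correlation). Cell cycle genes were higher with a median of 0.54 in 27 of 28 members, the mitotic cyclin CCNB1 at 63.5 ± 30.4 and 30.5 ± 3.23 CPM (adjusted p = 4.50e-10, and 0.542 with an estimated correlation). These 4 calls held without any 1 library. Interferon genes had a median of 0.60 (adjusted p = 0.0350, and 0.776 with an estimated correlation), lost without AS_2 (0.681, in the other direction), HC_2 (0.245) or HC_3 (0.66). Nuclear oxidative phosphorylation genes had a median of 0.19 (adjusted p = 0.0249, and 0.590 with an estimated correlation), lost without AS_1 (0.396) or HC_2 (0.174). Hemoglobin and erythroid genes had a median of -0.54 (adjusted p = 0.0492, and 0.590 with an estimated correlation), lost without AS_1 (0.279), AS_3 (0.296), HC_1 (0.256) or HC_2 (0.0985). Markers of CD8 T cells (adjusted p = 2.96e-19, and 0.052 by fry), CD4 T cells (9.63e-12, and 0.126), NK cells (0.0273, and 0.501) and monocytes (0.00880, and 0.205) were higher in AS within this class, and those of mature neutrophils (0.00134, and 0.501) and erythroid cells (0.00880, and 0.501) were lower. The rise of cytotoxicity genes therefore came together with T cell transcripts. The class joined clusters that the libraries filled unequally. A cluster of mixed identity, led by CTSG and MPO, had a median of 9343 UMIs per cell. It held 117 of 1669, 252 of 990 and 67 of 965 cells of AS_1 to AS_3. In HC_1 to HC_3 it held 248 of 3184, 98 of 901 and 129 of 2662. Apart from the immediate early list, the list and marker changes here were not separated from that mix.

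AS plasma cells had fewer transcripts of early response genes. DUSP2, a phosphatase that ends MAP kinase signals, averaged 11.2 ± 3.59 CPM in AS and 94.0 ± 45.4 CPM in HC (adjusted p = 0.118), NR4A1 7.71 ± 5.84 and 89.1 ± 37.4 CPM, and KLF6 42.4 ± 16.8 and 229 ± 92.0 CPM (adjusted p = 0.19 for both). DDIT4, an inhibitor of mTORC1, averaged 95.5 ± 36.8 and 29.5 ± 4.70 CPM (adjusted p = 0.25). TGM4, a transglutaminase, averaged 23.2 ± 13.6 CPM in AS and 0.0764 ± 0.132 CPM in HC (adjusted p = 0.0648). Of 5700 genes edgeR called 0. A total of 350 genes had an unadjusted p under 0.05, and DESeq2 called 42. Without AS_2 edgeR called 4 genes, RHOB and NR4A1 among them, without AS_3 it called 4, among them TGM4, TRAM2, DDIT4 and APOE, without HC_2 it called 3, and without HC_3 it called 1, DUSP2. The immediate early list had a median of -1.20 with 19 of 19 members below 0 and 12 lower over the list alone (adjusted p = 4.44e-22, and 0.196 with an estimated correlation). The TNF and NF-kB response had a median of -0.79, with CD83 at 7.72 ± 2.20 and 46.2 ± 41.0 CPM (adjusted p = 1.04e-04, and 0.477 with an estimated correlation). Cell cycle genes were higher with a median of 1.01 in 26 of 26 members, MCM5 at 32.6 ± 16.2 and 9.33 ± 7.75 CPM (adjusted p = 2.86e-10, and 0.568 with an estimated correlation). These 3 calls held without any 1 library. Complement genes had a median of -0.41 (adjusted p = 0.038, and 0.477 with an estimated correlation), lost without AS_2 (0.0871), HC_1 (0.264) or HC_2 (0.0673). Osteoclast genes had a median of -0.65, led by FOS and the phosphatase ACP5 at 61.0 ± 23.4 and 102 ± 44.7 CPM (adjusted p = 0.0363, and 0.477 with an estimated correlation), lost without AS_1 (0.102), AS_3 (0.062) or HC_1 (0.266). Glycolysis genes had a median of 0.34 (adjusted p = 0.0387, and 0.477 with an estimated correlation), lost without AS_1 (0.102), AS_3 (0.487), HC_1 (0.264) or HC_3 (0.138). Hemoglobin and erythroid genes had a median of -1.05 (adjusted p = 0.038, and 0.674 with an estimated correlation), lost without AS_1 (0.112), AS_3 (0.333), HC_1 (0.264) or HC_2 (0.204). Erythroid markers were lower in AS within this class too (adjusted p = 6.31e-04, and 0.384 by fry).

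SH3BP5, an adaptor that holds the kinase JNK at mitochondria, rose in AS CD4 T cells. It stood at 69.5 ± 24.4 CPM in AS and 8.50 ± 2.78 CPM in HC, a log2 change of 3.06 (SE 0.351, edgeR adjusted p = 0.0168), higher in 3 of 3 AS libraries than in any HC library. The gene ENSMFAG00000004354, which has no symbol in the files, rose from 29.6 ± 8.48 to 159.5 ± 18.5 CPM, a log2 change of 2.53 (SE 0.23, adjusted p = 0.0031), in 3 of 3 AS libraries. The same gene averaged 217 ± 107 and 39.6 ± 5.89 CPM in monocytes (adjusted p = 0.112) and 18.5 ± 4.99 and 25.1 ± 3.44 CPM in B cells (adjusted p = 1). PRDM1, which encodes the effector-cell repressor Blimp-1, averaged 57.6 ± 22.4 and 10.3 ± 4.33 CPM (adjusted p = 0.093), and FKBP5 190.5 ± 39.7 and 75.7 ± 15.7 CPM (adjusted p = 0.211). IL23A, which encodes the p19 subunit of IL-23, averaged 9.84 ± 4.67 CPM in AS and 15.8 ± 7.12 CPM in HC (adjusted p = 0.985). These 2 genes were the only calls of edgeR among 9066. At unadjusted p under 0.05 stood 464 genes, and DESeq2 called 14. Without AS_1 edgeR called 3 genes and without AS_2 it called 4, PRDM1 among them. It called 2 without AS_3, 1 without HC_1 or HC_3 and 0 without HC_2, so SH3BP5 was lost without any 1 of the HC libraries, and ENSMFAG00000004354 only without HC_2. SH3BP5 was also lost with age as a covariate, with each library clustered on its own, and without AS_2 and HC_3 together.

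Cell cycle genes were higher in AS CD4 T cells in 15 of 15 members, with a median of 0.90 and MCM7 at 25.8 ± 15.0 and 11.4 ± 2.38 CPM (adjusted p = 8.04e-05, and 0.752 with an estimated correlation), but not without AS_2 (0.245). Inflammasome genes had a median of 0.47 in 7 of 7 members, led by the cytokine IL18 at 31.4 ± 11.2 and 8.90 ± 4.87 CPM, which passed over the list alone (adjusted p = 2.69e-04, and 0.317 with an estimated correlation). That list held without any 1 library. Glucocorticoid response genes had a median of 0.48 with 3 higher over the list alone (adjusted p = 0.00101, and 0.565 with an estimated correlation), lost without AS_1 (0.135) or HC_2 (0.141). Chemokines and receptors had a median of 0.77, the marrow homing receptor CXCR4 at 190.4 ± 63.7 and 109 ± 18.7 CPM (adjusted p = 0.00648, and 0.565 with an estimated correlation), lost without HC_1 (0.179). The IL-17 and IL-23 axis had a median of 0.37 with 2 of 12 members higher over the list alone, BATF, a factor needed for Th17 cells, at 73.3 ± 19.8 and 33.7 ± 16.2 CPM, and IL18R1 at 13.1 ± 5.49 and 5.51 ± 2.78 CPM among its leading members (adjusted p = 0.0359, and 0.689 with an estimated correlation). That list was lost without AS_3 (0.116), HC_1 (0.0625) or HC_2 (0.277).

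CD8 T cells had 1 list that changed. Glucocorticoid response genes were higher with a median of 0.93 in 7 of 8 members and 2 passing over the list alone, CXCR4 at 300.4 ± 148 and 78.5 ± 34.0 CPM and FKBP5 at 228 ± 41.7 and 115 ± 44.3 CPM (adjusted p = 1.84e-07, and 0.332 with an estimated correlation). The call held without any 1 library, and between 3 and 7 lists were called then. SIGLEC6, a sialic acid receptor, averaged 37.6 ± 12 CPM in AS and 0.964 ± 1.67 CPM in HC (adjusted p = 0.0506), and PLAC8, a gene of activated leukocytes, 314 ± 122 and 72.3 ± 33.7 CPM (adjusted p = 0.246). Granzyme K, GZMK, averaged 1593 ± 247 and 695 ± 223 CPM (adjusted p = 0.733), and the kinase MATK 90.1 ± 24.9 and 221 ± 16.4 CPM (adjusted p = 0.242). Of the genes tied to ankylosing spondylitis risk in people, IL23R averaged 14.0 ± 9.63 CPM in AS and 11.4 ± 2.80 CPM in HC, ERAP1 58.4 ± 26.7 and 55.9 ± 13.1 CPM, and ERAP2 109.5 ± 22.9 and 74.2 ± 50.9 CPM (adjusted p = 1 for each). Of 7069 genes edgeR called 0. A total of 203 genes had an unadjusted p under 0.05, and DESeq2 called 7. Without AS_2 edgeR called 4 genes, SIGLEC6 and CXCR4 among them, and without HC_1 it called 5, SIGLEC6 and PLAC8 among them.

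B cells of AS animals had higher glucocorticoid response genes, with a median of 0.82 in 6 of 7 members and FKBP5 at 95.7 ± 35.1 and 42.9 ± 11.2 CPM, which passed over the list alone (adjusted p = 8.55e-05, and 0.191 with an estimated correlation). Granule protein genes, which belong to neutrophils, were lower with a median of -1.15 and 1 passing over the list alone, LTF at 13.1 ± 8.93 and 55.2 ± 11.1 CPM and CAMP at 43.5 ± 26.6 and 123 ± 55.7 CPM (adjusted p = 1.05e-05, and 0.191 with an estimated correlation). Glycolysis genes had a median of 0.31, the glucose transporter SLC2A3 at 78.9 ± 9.78 and 42.6 ± 21.3 CPM (adjusted p = 0.00318, and 0.191 with an estimated correlation). These 3 calls held without any 1 library. SESN1, a stress-induced inhibitor of mTORC1, averaged 146 ± 54.8 CPM in AS and 35.4 ± 15.3 CPM in HC (edgeR adjusted p = 1, DESeq2 adjusted p = 0.00867). Of 7984 genes edgeR called 0, 1 without AS_2 and 1, CXCL10, without AS_3. At unadjusted p under 0.05 stood 167 genes, and DESeq2 called 3. Ribosomal protein genes had a median of 0.24 in 20 of 21 members (adjusted p = 0.00823, and 0.408 with an estimated correlation), lost without HC_1 (0.115). Complement genes had a median of 0.40 (adjusted p = 0.0486, and 0.379 with an estimated correlation), lost without AS_2 (0.0957), AS_3 (0.551), HC_1 (0.151) or HC_2 (0.279). Cell cycle genes had a median of -0.35 (adjusted p = 0.0486, and 0.691 with an estimated correlation), lost without AS_1 (0.129), AS_2 (0.0578) or HC_3 (0.955, in the other direction). B precursor markers were lower in AS B cells (adjusted p = 0.00137, and 0.734 by fry).

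Erythroid cells of AS animals had higher glucocorticoid response genes, with a median of 0.70 in 6 of 7 members (adjusted p = 8.52e-05, and 0.213 with an estimated correlation). Each AS library had a higher mean of this list than each HC library, with 4.10, 4.47 and 4.60 against 3.83, 3.68 and 3.91 on the log2(CPM + 1) scale. Immediate early genes were lower with a median of -0.45, FOS at 58.9 ± 36.7 and 138 ± 30.9 CPM (adjusted p = 1.26e-05, and 0.343 with an estimated correlation). Of the 3 erythroid clusters tested alone, 1 had a lower list, with a median of -0.60 (adjusted p = 0.000154, and 0.662 with an estimated correlation), and the others had medians of 0.07 (0.635) and 0.12 (0.435). Cytotoxicity genes were higher with a median of 0.83 and 2 of 5 members passing over the list alone, GZMB at 11.4 ± 12.3 and 1.05 ± 0.825 CPM and NKG7 at 7.04 ± 6.93 and 0.659 ± 0.368 CPM among them (adjusted p = 2.48e-04, and 0.213 with an estimated correlation). The first 2 of these calls held without any 1 library. So did the cytotoxicity call, except that without AS_2 too few of its members were measured to test it. SERPINB6, a protease inhibitor, averaged 87.8 ± 33.1 CPM in AS and 0.896 ± 0.953 CPM in HC, and TP53I3, a target of p53, 12.8 ± 4.04 and 0.429 ± 0.389 CPM (adjusted p = 0.241 for both). Of 9295 genes edgeR called 0, 1 without AS_2 and 6, SERPINB6 and TP53I3 among them, without HC_2. A total of 165 genes had an unadjusted p under 0.05, and DESeq2 called 11. MHC class I genes had a median of 0.40 (adjusted p = 6.46e-05, and 0.678 with an estimated correlation), lost without AS_2 (0.37). Complement genes had a median of 0.33 (adjusted p = 0.01004, and 0.343 with an estimated correlation), lost without HC_2 (0.27) or HC_3 (0.0691). Heat shock genes had a median of -0.16 (adjusted p = 0.0335, and 0.678 with an estimated correlation), lost without AS_1 (0.0702), AS_3 (0.341) or HC_2 (0.541). Mitochondrially encoded genes had a median of -0.13 (adjusted p = 0.0102, and 0.679 with an estimated correlation), lost without AS_1 (0.237), AS_2 (0.0556), HC_1 (0.0567) or HC_3 (0.279). Markers of basophils, mast cells and eosinophils were higher in AS within this class (adjusted p = 3.29e-15, and 0.189 by fry).

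**Figure D4:**
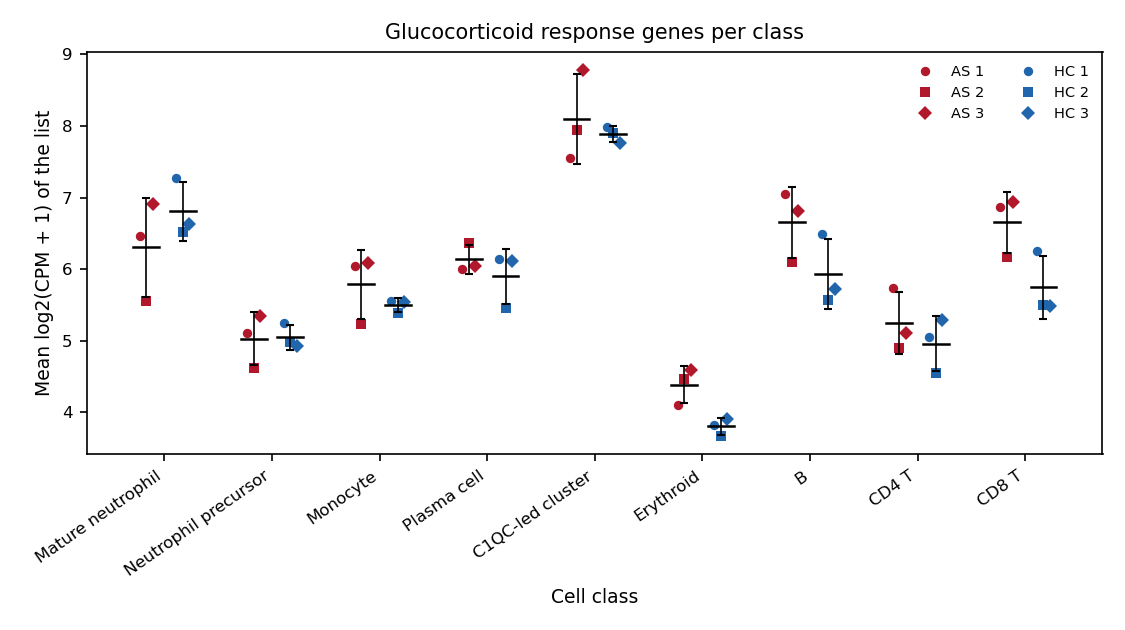
Mean log2(CPM + 1) of the glucocorticoid response genes in 9 cell classes. Circles, squares and diamonds are the libraries with replicate numbers 1, 2 and 3, red for AS and blue for HC, with the mean and SD of 3 animals in black. In erythroid cells the AS libraries lie at 4.10, 4.47 and 4.60 and the HC libraries at 3.83, 3.68 and 3.91, and in the other classes the groups overlap.

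The C1QC-led cluster had higher MHC class II genes in AS, with a median of 0.76 in 6 of 8 members and 4 passing over the list alone. HLA-DRA averaged 3140.0 ± 1290.0 CPM in AS and 909.5 ± 405 CPM in HC, HLA-DMB, which loads peptides, 150.4 ± 41.3 and 41.1 ± 17.3 CPM, and the invariant chain CD74 12700.0 ± 3800.0 and 5900.0 ± 2560 CPM (list adjusted p = 6.94e-05, and 0.326 with an estimated correlation). Immediate early genes were lower with a median of -0.72, BTG2 at 173 ± 108 and 701 ± 355 CPM (adjusted p = 6.04e-06, and 0.346 with an estimated correlation). These 2 calls held without any 1 library. TNFRSF1A, a receptor for TNF, averaged 98.2 ± 37.8 and 125 ± 38.0 CPM (adjusted p = 0.974). Of 1999 genes edgeR called 0, and 4 without AS_3, HLA-DQA1 among them. At unadjusted p under 0.05 stood 96 genes, and DESeq2 called 0. MHC class I genes had a median of 0.41 (adjusted p = 0.00574, and 0.346 with an estimated correlation), lost without AS_2 (0.18), HC_2 (0.0629) or HC_3 (0.0568). Inflammasome genes had a median of 0.56 (adjusted p = 0.0172, and 0.326 with an estimated correlation), lost without AS_1 (0.0674), AS_2 (0.0815), HC_1 (0.193), HC_2 (0.0556) or HC_3 (0.0568). Unfolded protein response genes had a median of 0.24 (adjusted p = 0.0103, and 0.346 with an estimated correlation), lost without AS_2 (0.0815), AS_3 (0.0796) or HC_3 (0.214). Mitochondrially encoded genes had a median of -0.65 in 13 of 13 members (adjusted p = 8.10e-04, and 0.531 with an estimated correlation), lost without AS_1 (0.099) or HC_1 (0.753). The least populated library held 30 cells of this cluster.

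All cells summed mix composition with expression. T cell, NK and monocyte genes stood higher and erythroid and neutrophil genes lower in AS, as the markers did: CD4 T and CD8 T markers (adjusted p = 8.79e-05 for both), NK markers (0.0180) and monocyte markers (1.63e-05) were higher. Markers of erythroid cells (7.53e-06), stem and progenitor cells (2.66e-05), B precursors (0.00122), neutrophil precursors (0.00337) and mature neutrophils (0.00559) were lower. By fry these had adjusted p values of 0.653 for NK and neutrophil precursor markers, 0.191 for stem and progenitor cells and 0.595 for the others. NR4A1 averaged 4.91 ± 1.73 CPM in AS and 24.8 ± 2.11 CPM in HC, FKBP5 98.3 ± 7.31 and 37.5 ± 9.53 CPM, and CCR2 37.1 ± 15.6 and 10.2 ± 1.32 CPM (adjusted p = 0.709 for each). Of 13076 genes edgeR called 0, with all 6 libraries and without any 1 of them. A total of 717 genes had an unadjusted p under 0.05, and DESeq2 called 121. Cell cycle genes were lower with a median of -0.74 in 28 of 28 members (adjusted p = 6.47e-15, and 0.433 with an estimated correlation), and hemoglobin and erythroid genes with -0.97 in 7 of 7 (4.36e-05, and 0.433 with an estimated correlation). Interferon genes were higher with a median of 0.47 and 4 over the list alone (adjusted p = 2.56e-07, and 0.433 with an estimated correlation). Glucocorticoid response genes had a median of 0.82 with 3 over the list alone (2.05e-05, and 0.371 with an estimated correlation). The IL-17 and IL-23 axis had a median of 0.63 with 2 over the list alone, IL12RB1 at 3.41 ± 0.953 and 1.07 ± 0.292 CPM (adjusted p = 2.24e-04, and 0.180 with an estimated correlation). Risk loci of ankylosing spondylitis had a median of 0.29 in 17 of 24 members above 0, LTBR at 34.8 ± 17.1 and 14.2 ± 3.14 CPM (adjusted p = 0.00173, and 0.433 with an estimated correlation). MHC class I genes had a median of 0.41 (1.49e-04, and 0.433 with an estimated correlation), T cell regulation genes 1.04 (1.58e-04, and 0.180), chemokines and receptors 0.84 (4.36e-05, and 0.180) and complement genes 0.82 (0.00170, and 0.180). Over the list alone 5 chemokine genes were higher, 2 were lower, and 1 complement gene was higher. These 10 calls held without any 1 library. The TNF response with a median of -0.63 (0.00148, and 0.433 with an estimated correlation) and immediate early genes with -0.60, 1 lower over the list alone (6.74e-06, and 0.433), were lost without AS_2 (0.326 for both). MHC class II genes with a median of 0.60 (5.31e-04, and 0.433) were lost without AS_3 (0.0911), and cytotoxicity genes with 0.98 (4.36e-05, and 0.433) without AS_1 (0.179). Granule protein genes with -1.07 (0.00333, and 0.542) were lost without AS_2 (0.0948) or HC_1 (0.893). The risk loci list was called in no single class, and IL17A was not measured in any class tested.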

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

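The mean of the complement genes rose in AS B cells and was lower in AS plasma cells, and a rule that compares a list between classes marked the pair. The change on the log2(CPM + 1) scale was larger in B cells than in plasma cells by 1.299. The difference itself was not tested. With an estimated correlation the adjusted p was 0.379 in B cells and 0.477 in plasma cells. Both calls were lost without AS_2 (0.0957 and 0.0871), HC_1 (0.151 and 0.264) or HC_2 (0.279 and 0.0673), and that of B cells also without AS_3 (0.551). The members measured differed between the 2 classes.

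An unnamed cluster of 29 cells was found only in AS_2, where it made up 0.4226% of cells (exact 95% interval 0.2832 to 0.6063%). A rule for data left out of the comparisons marked it. In AS_1, AS_3, HC_1, HC_2 and HC_3 it had 0 cells, which at a limit of 3 cells allows shares of up to 0.0389, 0.0656, 0.0335, 0.0691 and 0.0530%.

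The same rule marked an unnamed T-like cluster with 982 cells in AS_1, 12.72% of that library (exact 95% interval 11.98 to 13.48%). PRSS57, KLRD1, IL2RB, FCRL6, EOMES, KLRK1 and TOX led it. It made up 0.0729% of AS_2, 0.0437% of AS_3, 0.123% of HC_1, 0.553% of HC_2 and 0.0354% of HC_3, so it was an event of 1 animal. Counting it as CD8 T cells gave CD8 T shares of 10.0 ± 12.3% in AS and 3.06 ± 1.78% in HC (exact permutation p = 0.6).

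The lower immediate early genes in AS monocytes, neutrophils and plasma cells were weighed against 4 technical explanations. The fits with depth, and the look at clusters of monocytes and mature neutrophils, were chosen after seeing the data. The planned count on depth decides nothing: 8 of 8 AS values with HC-like depth lay below every HC library, but the classes had been picked for lying apart. A linear fit of the list mean on group and log2 of the median UMIs per cell was run instead. Beside depth, AS minus HC was -2.38 in mature neutrophils (SE 0.413, 95% interval -3.69 to -1.07), -1.07 in neutrophil precursors (SE 0.264, -1.91 to -0.23) and -1.77 in plasma cells (SE 0.145, -2.24 to -1.31). Without depth in the fit the differences were -2.17, -1.07 and -1.38, so they did not shrink beside it in these libraries. The same picking of classes bears on the intervals, which therefore cannot show that depth was not the source. Only 1 AS library of plasma cells had HC-like depth. In monocytes the fit gave -1.41 (SE 0.527, -3.09 to 0.27), again with 1 such library. Depth stayed open in each of these classes. A different mix of clusters was not the whole source in neutrophil precursors, where the list median lay below -0.5 in 4 of 4 clusters with at least 20 cells in every library. Their 2 other clusters, with 561 and 1011 of the 3184 cells of HC_1, could not be tested, and 0 clusters of monocytes and mature neutrophils had enough cells to look, so the mix stayed open there. RNA free in the suspension from neutrophils was not the only source of these transcripts in HC plasma cells. The ratio of the list to S100A8 there was at least 4.203 times that in HC mature neutrophils, and 2114 times at most, in HC_2. The ratio sums members that plasma cells may express themselves, so it cannot tell whether free RNA made part of the difference. Free RNA from other cells was not looked at. Handling before lysis, to which these genes respond, stayed open: in CD4 T, CD8 T and B cells the list median lay between -0.1101 and 0.1328, and the labels give no handling times.

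The higher glucocorticoid response genes in AS were weighed against 2, and all tests but the planned count on depth were chosen after seeing the data. In that count 4 of 4 AS values inside the HC depth range lay above every HC library. It decides nothing, since 3 came from erythroid cells, which already lay apart, and 1 from monocytes, where AS_1 had 10025 UMIs and the deepest HC library 10042. The deepest AS library of monocytes, AS_2, had a list mean of 5.24, below each HC library (5.39 to 5.56). The linear fit with depth gave an AS minus HC difference of 0.455 in monocytes (SE 0.448, 95% interval -0.97 to 1.88) and 0.57 in erythroid cells (SE 0.197, -0.06 to 1.2), so depth stayed open in both. In lymphocytes 0 of 9 AS values lay inside that range, since AS cells were deeper in each, and depth stayed open there. RNA free in the suspension stayed open too, since the list in AS CD4 T cells stood at 0.6002 to 1.498 times its level in all cells summed. A different mix of clusters was not weighed for this list, and it stayed open in monocytes and erythroid cells. Mature neutrophils did not share the rise, with a list mean of 6.31 ± 0.69 in AS and 6.81 ± 0.41 in HC, nor did their precursors, with 5.03 ± 0.37 and 5.05 ± 0.17. The list as written shares DUSP1 and SGK1 with the immediate early list, which was lower in AS in both classes. How far these genes held the mean down was not tested.

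The T cell transcripts in AS neutrophil precursors pointed to whole T cells in that class, as doublets or misplaced cells. Cells with both CD3D and CD3E were 35.54 to 107.2 times as frequent in AS libraries as independent draws give, and 41.6 to 76.1 times in HC libraries, where the 76.1 of HC_3 rests on 1 cell (95% interval 1.93 to 424). CD3D was found in 2.16, 2.02 and 0.622% of AS cells and 0.911, 1.44 and 0.263% of HC cells of the class. Free RNA from T cells, spread evenly over cells, would not put both genes into the same cells. CD3D in the class nevertheless followed CD3D in all cells with a rank correlation of 0.771 over 6 libraries. The draws took no account of depth, and clusters of the class had medians from 1275 to 9343 UMIs per cell. A part of the excess could thus come from deep cells, and free RNA stayed open as a part of the source. The excess was present in HC too, so by itself it does not bear on the rise in AS.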

How the results depend on the processing

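The number of genes called depended on the count filter and single libraries. Fold changes of named genes were looked at with DESeq2 and with 1 library left out only. Of these pairs of gene and alternative, 2431 stayed the same, 127 were stronger, 11 weaker and 15 reversed. Most of these genes had been named for a small p or as leading list members in the same libraries. A kept direction was thus largely set in advance and is no evidence of stability. Of the numbers of genes called, 76 moved and 84 stayed, and of the numbers of lists called, 37 moved and 73 stayed. Single lists stayed the same in 524 cases, were weaker in 262 and reversed in 5. Shares kept their sign in 150 cases and reversed in 24. Of the 150, 14 came from the replicate block, which leaves the difference itself unchanged and could not reverse it. The cause of most moves was not tested. The stricter cell filter left too few cells of the C1QC-led cluster, and clustering each library on its own gave no testable CD8 T class, so these have no value.

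DESeq2 was run without the count filter and with its own independent filtering, so tool and filter changed together. It called 3 genes in B cells, 14 in CD4 T cells, 7 in CD8 T cells, 11 in erythroid cells, 74 in mature neutrophils, 155 in monocytes, 56 in neutrophil precursors, 42 in plasma cells, 121 in all cells and 89 in cluster 21, a cluster of neutrophil precursors led by CTSG and MPO. Without the count filter edgeR called 2 genes in B cells, 70 in the C1QC-led cluster, 11 in CD4 T cells, 46 in CD8 T cells, 3 in erythroid cells, 40 in mature neutrophils, 26 in monocytes, 39 in plasma cells, 100 in cluster 21, and 0 in neutrophil precursors and all cells. On these same genes edgeR called more than DESeq2 in CD8 T cells, the C1QC-led cluster and cluster 21, and fewer in the other classes and all cells. With DESeq2 size factors CD8 T cells had 1 gene, and so they did with the unnamed T-like cluster counted among them. With age as a covariate CD4 T cells had 1 gene, and mature neutrophils and monocytes had 0. Without doublet removal the C1QC-led cluster had 1 and monocytes had 0. The stricter cell filter gave 4 in CD4 T cells, 1 in CD8 T cells, 9 in mature neutrophils, 0 in monocytes and 3 in plasma cells. Clustering each library on its own gave 1 in CD4 T cells and 0 in mature neutrophils and monocytes.

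With 1 library left out at a time, the genes called ranged from 0 to 1 in B cells, 0 to 4 in the C1QC-led cluster, CD4 T cells and plasma cells, 0 to 5 in CD8 T cells, 0 to 6 in erythroid cells, 0 to 3 in mature neutrophils, 0 to 74 in monocytes and 0 to 29 in cluster 21. Without both AS_2 and HC_3, the 2 libraries that stood apart, mature neutrophils had 4, TNF among them, neutrophil precursors 1, plasma cells 9 and cluster 21 had 2. The 1 gene of monocytes was then CPVL and not NR4A1.

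The replicate numbers name different animals, and the correlations of same-numbered libraries in all cells were -0.251, -0.148 and 0.13. In neutrophil precursors all 3 were above 0.1, with 0.141, 0.434 and 0.234, and in no other class. A replicate block, run as planned, gave 2 genes in the C1QC-led cluster, 14 in CD4 T cells, 2 in CD8 T cells, 1 in erythroid cells, 2 in mature neutrophils, 0 in monocytes, 3 in neutrophil precursors, 5 in plasma cells and 11 in cluster 21. The 2 in mature neutrophils were EGR1 and ENSMFAG00000044412, so the TNF call was lost, as was NR4A1 in monocytes.

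With an estimated correlation camera called 0 lists in each of the 9 classes (B cells, the C1QC-led cluster, CD4 T cells, CD8 T cells, erythroid cells, mature neutrophils, monocytes, neutrophil precursors and plasma cells) and 0 in all cells, and fry called 0 in each as well. Without AS_2 and HC_3 the preset correlation called 10 lists in B cells, 8 in CD4 T cells and 7 in CD8 T cells. With age as a covariate it called 4 in plasma cells. With 1 library left out it called 3 to 10 lists in CD4 T cells, 3 to 7 in CD8 T cells, 6 to 11 in erythroid cells, 7 to 13 in mature neutrophils and 3 to 7 in plasma cells. Cell cycle genes in B cells reversed without AS_2 and HC_3 (adjusted p = 0.84), and with 1 library left out their adjusted p ranged from 0.000292 to 0.955. The interferon list reversed without AS_2 and HC_3 in monocytes (adjusted p = 0.449) and in neutrophil precursors (adjusted p = 0.0204), where leaving out 1 library gave 3.38e-05 to 0.681.

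Differences of shares changed sign in several classes. Under the stricter cell filter B cells differed by -0.07581 percentage points and CD4 T cells by -0.9775. Without erythroid cells and neutrophils in the denominator B cells differed by -2.731, CD4 T cells by -6.843, monocytes by -2.405 and stromal or endothelial cells by -0.06677. On that denominator plasmacytoid dendritic cells held 0.541% in AS and 1.896% in HC, and B precursors 0.518% and 2.721%, each with an exact permutation p of 0.1, the smallest possible. It still held the 983 unnamed cells of AS_1, nearly all from the T-like cluster of that animal, which lowered the AS_1 shares. Whether the groups stay apart without these cells was not tested. No doublet removal gave -0.1048 for stromal or endothelial cells, and clustering each library on its own gave -0.9839 for mature neutrophils. In that setting 761 cells of AS_1 and 213 of HC_1 scored best as mature neutrophils but stayed unnamed. The 942 cells of HC_3 led by PPBP, SOD2, G0S2 and PF4 were named megakaryocytes. None of these cells counted as mature neutrophils, so the change of sign may come from the naming. With 1 library left out the difference ran from -1.218 to 4.092 for B cells, -0.9019 to 0.01142 for B precursors, -0.6916 to 1.53 for the C1QC-led cluster, -1.728 to 4.196 for CD4 T cells and -4.528 to 13.65 for mature neutrophils. It ran from -0.2118 to 1.69 for megakaryocytes, -0.7095 to 9.547 for monocytes, -0.0692 to 3.597 for NK cells, -0.8852 to 0.291 for plasma cells and -0.06886 to 0.1219 for stromal or endothelial cells. Without a change of sign, it ran from -12.59 to -1.498 for erythroid cells, 0.06617 to 4.972 for CD8 T cells, -22.27 to -9.112 for neutrophil precursors and -0.285 to -0.1518 for plasmacytoid dendritic cells. Clustering each library on its own gave -5.772 for neutrophil precursors and -3.706 for erythroid cells. In that setting HC_1 clusters of 315, 407 and 481 cells scored best as erythroid but stayed unnamed, as did 75 cells of AS_2. These cells were not counted in the erythroid share. Joining neutrophils gave 47.0 ± 14.9% in AS and 57.7 ± 20.5% in HC (exact permutation p = 0.7).

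Some fold changes reversed with 1 library left out, large ones among them. On the log2 scale IL23R in CD8 T cells ran from -0.6072 to 0.6606, with 0.1589 by DESeq2, and ERAP1 there from -0.2722 to 0.2878. STMN1 in B cells ran from -1.041 to 0.05657, CTSW in erythroid cells from -1.165 to 0.1985, LTF in mature neutrophils from -0.0956 without AS_2 to 2.955, HEMGN in neutrophil precursors from -0.6207 to 0.1004 and S100A8 there from -0.692 to 0.2494. C2 in plasma cells ran from -0.7173 to 0.4497 and C1QC in all cells from -0.1915 without AS_2 to 1.472.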

Other observations

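A cluster of 911 neutrophil precursors, led by CTSG, MPO and AZU1, was tested by itself after the data were seen. Its identity was mixed: the mean z-score was 1.67 for conventional dendritic cell markers and 0.861 for neutrophil precursors, the name came from markers among its leading genes, and CLEC9A was among them too. BTG2 fell in AS from 358 ± 36.7 to 94.7 ± 25.1 CPM (edgeR adjusted p = 0.00849), NR4A1 from 22.8 ± 8.45 to 1.62 ± 0.282 CPM (0.0111), KLF4 from 262 ± 62.8 to 90.5 ± 13.8 CPM (0.0159) and ZFP36, which destabilises cytokine mRNA, from 1387 ± 141 to 526 ± 149 CPM (0.0481). The scavenger receptor CD163 rose from 31.6 ± 5.95 to 115 ± 28.2 CPM (adjusted p = 0.0142), and the kinase PIM1 from 11.7 ± 3.51 to 54.5 ± 22.6 CPM (0.0458). GIMAP7, a GTPase of lymphocytes, rose from 17 ± 6.31 to 75.8 ± 13 CPM (adjusted p = 0.013) and CD3D from 5.49 ± 3.82 to 69.6 ± 24.1 CPM (0.022), so T cell transcripts moved in this cluster too. In all, edgeR called 28 of 7794 genes, 13 higher and 15 lower, with 756 at unadjusted p under 0.05 and 89 by DESeq2. The immediate early genes had a median log2 change of -1.40 with 21 of 21 members below 0 (camera adjusted p = 1.06e-25, and 0.151 with an estimated correlation).

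This cluster was picked for having the most calls of 12 tested alone, and no correction was made over clusters. Its calls were 17 without AS_1, 5 without AS_2, 27 without AS_3, 20 without HC_1, 29 without HC_2 and 0 without HC_3. Size factors of DESeq2 gave 27 and age as a covariate 25, of which 20 were among the 28. The replicate block gave 11, with 7 among the 28, and leaving out AS_2 and HC_3 together gave 2, with 0 among them. Among the 10 splits of the 6 libraries into 3 and 3, the real one called 28 genes and the highest other called 1. The cluster had been picked for its calls in the real split, so that contrast favours the real split and decides nothing. In cluster 17, which holds erythroid cells, TP53I3 rose from 0.635 ± 0.667 to 27.5 ± 7.73 CPM (edgeR adjusted p = 0.00967). There 3 of the 10 splits, the real split included, called at least as many, and the highest other called 2.

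The splits of the libraries were compared with the real groups after the calls were known. With 10 splits the share of splits with as many calls cannot fall under 0.05. Mature neutrophils and monocytes each had 1 gene in the real split and 0 in any other. CD4 T cells had 2, and 3 splits, the real split included, reached that number, the highest other with 2. In the classes with 0 real calls all 10 splits had as many, and the highest other called 83 genes in B cells, 1 in the C1QC-led cluster, 2 in CD8 T cells, 1 in erythroid cells, 1 in neutrophil precursors, 4 in plasma cells and 1 in all cells. The 83 genes in B cells set AS_1, AS_2 and HC_1 against the other 3 libraries, which points to a structure of the samples in B cells. What these libraries share was not tested.

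For gene lists no class, nor all cells summed, had the most calls in the real split alone. The counts of splits here include the real split and those with more lists. In B cells the real split called 6 lists, 5 splits had at least as many, and the highest other had 8. In the C1QC-led cluster it called 6, with 2 splits and 7. CD4 T cells had 5, with 9 splits and 14, CD8 T cells 1, with 10 splits and 10, and erythroid cells 7, with 4 splits and 11. Mature neutrophils had 8, with 2 splits and 9, monocytes 10, with 3 splits and 13, and neutrophil precursors 7, with 5 splits and 8. Plasma cells had 7, with 2 splits and 7, and all cells 15, with 2 splits and 17. A number of called lists is therefore no evidence of disease by itself, since another split called more in 9 of the 10 sums and as many in plasma cells.

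The first hypothesis is that marrow myeloid cells and plasma cells of AS animals carried less recent stimulation than those of controls. The pattern was noticed in the results, and the fits with depth and the look at clusters of monocytes and mature neutrophils were chosen after seeing the data. Beside depth the difference of the list mean was -2.38 in mature neutrophils, -1.07 in their precursors and -1.77 in plasma cells. Each 95% interval lay below 0, but the classes had been picked for lying apart, so the fits do not decide on depth. In 4 of 4 precursor clusters with enough cells the median was under -0.5, and 2 others, which held 561 and 1011 of the 3184 cells of HC_1, could not be tested. The mix of clusters stayed open in mature neutrophils and monocytes, depth in all these classes, and a part from free RNA in plasma cells. The same result could come from samples of the HC group that waited longer or warmer before lysis, because immediate early genes respond to that. CD4 T, CD8 T and B cells did not share the change, with list medians from -0.1101 to 0.1328, but myeloid cells may respond to handling more than lymphocytes do. Erythroid cells and the C1QC-led cluster had lower immediate early genes as well, with medians of -0.45 and -0.72. The change was thus not confined to the classes named here. Among erythroid clusters tested alone the list was lower only in cluster 17 (median -0.60), against 0.07 and 0.12 in clusters 16 and 28. Collection times of each animal would help to settle the question of handling.

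The second and weaker hypothesis is a higher glucocorticoid response in some cell classes of AS animals, through disease stress or a treatment that the labels do not name. FKBP5 was higher in AS CD4 T cells, CD8 T cells, B cells and monocytes, and passed over its list in each of these. In monocytes this was not separated from the mix of clusters. The cluster that held most AS_1 and AS_3 monocytes was led by CD163, itself a member of the list, and had 6, 6 and 8 cells in HC_1 to HC_3. A tone of the whole animal would be expected in neutrophils too. There the list mean differed by -0.50 in mature neutrophils and -0.02 in their precursors. The list shares DUSP1 and SGK1 with the immediate early list, which was lower in both classes, so these values do not decide the matter. Tests chosen after the data were seen left depth open. In lymphocytes 0 of 9 AS values had HC-like depth, and beside depth the difference was 0.57 in erythroid cells and 0.455 in monocytes, with 95% intervals that hold 0. A free RNA ratio of 0.6002 to 1.498 leaves that source possible as well. Serum cortisol and treatment records would test it.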
